A study of Homo sapiens with 8 samples.

How the data were processed

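RNA from 8 cultures of U6A cells was measured on Illumina bead arrays after biotin labelling, per the labels. U6A is a human fibrosarcoma line that lacks STAT2, and the cells expressed either wild-type STAT2 or STAT2 with the T387A substitution. Each of the 2 lines was sampled at 0, 4, 8 and 24 h of interferon-beta (IFN-β) at 100 IU/ml, per the labels' protocols, which gives 1 array per line and time. Groups were taken from the sample titles and the genotype labels. The labels name no culture batch, chip or scan.

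The values are linear probe intensities as deposited by the authors in 1 table of the 8 arrays. GenomeStudio is named in the submitters' processing notes, and its version, its background and normalization settings and any detection filter are not given in the sources used here. The values themselves show that background had been subtracted, since 28.6% of them were at or below 0 and the lowest was -19.9. They also show that the arrays had been quantile-normalized to each other, since 78.6% of the ranks held identical values on all 8 arrays and the largest difference between columns at a rank was 0.6. No further normalization between arrays was therefore applied, and the summed intensity of an array carries no information about its RNA input.

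Of the 47315 probes, 30111 carried 1 gene symbol in the probe table, 8 carried several and 17196 carried none. The symbols were set against current gene identifiers, which changed 0 of them and left 39 probe symbols without a current identifier. Probes with several symbols or none were left out of all gene results. The remaining probes named 20045 genes, and for the 6691 genes with more than 1 probe the probe with the highest mean intensity over the 8 arrays stood for the gene.

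Values under a floor of 10.7 were set to 10.7 and log2 was taken. The floor was the larger of the median of all values, 6.1, and the size of the value at percentile 1, which was -10.7. A gene was tested if it was above the floor on at least 1 array, which left 13656 genes. A fold against arrays at the floor, whether all arrays of a group or some, is a lower bound and is written as at least N-fold. A difference of 2 responses with arrays at the floor is not a bound. Medians of gene lists hold such members at that bound.

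Limma's lmFit and eBayes with Benjamini-Hochberg adjustment tested 4 comparisons on all 8 arrays, at an adjusted p under 0.05. The interferon response was fitted as genotype plus treated, with the 6 arrays at 4, 8 and 24 h against the 2 at 0 h. The genotype difference was fitted as time plus genotype, with 4 arrays against 4. The difference of the responses was the interaction of genotype and treatment, in which each untreated arm holds 1 array that is assumed to vary like the treated ones and time is not a term. The late response was 24 h minus 4 h in the fit of time plus genotype. Single times and single lines have no replicates and no test: they are given as log2 differences, counts of genes changed at least 2-fold, and the percentile of a gene list's median among 10000 random lists of the same size matched on mean level.

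The comparisons, 29 gene lists, the rule for named genes and most alternatives were set before the data were examined. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the residuals. In tested comparisons the rule names the 10 largest changes each way among genes past the threshold with one sign at every time compared. In untested comparisons it names the 10 largest changes each way among genes above the floor with one sign at every time compared. It also names up to 4 members of each list described, and single genes set beforehand, among them STAT2, IRF9, USP18, SOCS1, IFIT1, MX1, OAS1, ISG15, IFI27 and CXCL10. STAT2 was not analysed here.

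The alternatives set beforehand were a scaling between arrays, a doubled floor of 21.4, no floor with an offset of 16 added to the shifted values, a filter requiring 4 arrays above the floor, the mean of a gene's probes, a trended and robust prior, omission of single arrays or of both arrays of a time, a genotype fit without time, the estimated correlation, and a threshold of 1.5-fold. Those chosen after seeing the data were a floor at an intensity of 100, cyclic loess between arrays, and time as 4 levels with each treated time against 0 h. For the interaction they were also the floor kept with the offset of 16 and time as 4 levels. The 1.5-fold threshold was set beforehand for each line and for the differences between them, and afterwards for genes changed in both lines.

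The fits and the random lists were tested on simulated data with the residual spread of each level class, in which 50 genes each were changed 1.5-, 2-, 4- and 8-fold. The changed genes were drawn only from those with a mean level over 50, and each changed by the same amount on every array it changed on. The shares below therefore do not cover dimmer genes or responses that vary with time. The interferon fit, run on 13653 genes, called 34.0% of the genes changed 1.5-fold, 98.0% of those changed 2-fold and 100.0% of those changed 4-fold, and 17 of its 183 calls were unchanged genes. The genotype fit, run on 13651 genes, called 42.0%, 98.0% and 100.0% at these sizes, and 8 of its 178 calls were unchanged genes. The interaction, run on 13649 genes, called 0.0%, 2.0% and 92.0%, and the late contrast, on as many genes, called 2.0%, 68.0% and 100.0%. In each of the latter fits 4 calls were unchanged genes, of 100 calls for the interaction and 139 for the late contrast. The simulated genes of a level class shared 1 spread, whereas real genes of a class differ in theirs. These shares may therefore be too high, and the numbers of unchanged genes called too low, which was not tested. Of 60 unchanged random lists 1 fell outside the central range, and all 60 lists shifted by 0.5 on the log2 scale fell above it. The simulated genes varied independently of each other, whereas the antiviral list had an estimated correlation of 0.442 in the genotype fit. This simulation therefore does not test the percentiles of lists whose members move together.

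The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.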

Results

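Gene expression was measured on 8 bead arrays of total RNA from U6A cells, human fibrosarcoma cells without endogenous STAT2, that expressed wild-type STAT2 or its T387A mutant. STAT2 acts with IRF9 as a transcription factor in the response to type I interferons. Each line was sampled at 0, 4, 8 and 24 h of IFN-β at 100 IU/ml, with 1 array for each of the 8 combinations. The question that the design poses is how IFN-β changes gene expression in each line and where the lines differ. STAT2 itself was not analysed here, so the genotype labels were not checked against its level. The intensities had been equalised between arrays before deposit: the sums ran from 10093323 to 10094142, and 40.2 to 40.3% of probes were above the floor of 10.7 on each array. Single arrays correlated with the others at a mean Pearson r of 0.981 to 0.986 across the 27163 probes above the floor on any array.

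There were no replicates of any line and time, and the number of arrays limits the precision. The yardstick for error was the residual SD of the fit of time plus genotype, which was 0.319 on the log2 scale for the 6352 genes with a mean level under 50 and 0.103 for the 1165 genes above 1000. A difference between 2 single arrays then has an SD of 0.451 for the dimmest class and 0.146 for the brightest. P-values measure only the spread between these arrays, which holds differences between times and between lines as well as technical spread.

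IFN-β raised antiviral genes over both lines. IFIT3 rose by 6.75 ± 0.42 on the log2 scale (SE, 6 treated against 2 untreated arrays), or 107.5-fold, and IFIT1 by 5.92 ± 0.36, with limma adjusted p = 0.00505 for each; both belong to a family that binds viral RNA. IFIT2 rose by 6.03 ± 0.53, OAS2, which makes the 2'-5' oligoadenylates that activate RNase L, by 5.62 ± 0.56, and OASL by 5.12 ± 0.48. The RNA sensors RIGI and IFIH1 rose by 4.75 ± 0.49 and 4.64 ± 0.49. RSAD2, which encodes viperin, was at the floor on both untreated arrays and rose at least 73.0-fold, and RTP4 rose at least 16.6-fold. IRF9, the DNA-binding partner of STAT2, had the smallest adjusted p, 0.00452, with a rise of 3.25 ± 0.17 or 9.48-fold.

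Antiviral effectors and related lists rose in this comparison. Of 32 antiviral effectors 7 rose over all genes tested and 24 when adjusted over the list alone, all 32 had positive estimates, and their median change was 3.04 (camera adjusted p = 1.09e-37, and adjusted p = 0.15 with an estimated correlation). Of 11 genes of ISG15 conjugation 2 rose over all genes and 9 adjusted over the list alone, with a median of 2.49 (adjusted p = 9.75e-16, and adjusted p = 0.15 with an estimated correlation). Of 12 nucleic acid sensors 2 rose over all genes and 7 adjusted over the list alone (adjusted p = 1.67e-09, and adjusted p = 0.193 with an estimated correlation). None of the 17 genes of class I antigen presentation passed over all genes, 2 rose adjusted over the list alone, and the median was 0.77 (adjusted p = 2.07e-07, and adjusted p = 0.394 with an estimated correlation). The 8 negative regulators of interferon signalling had 4 positive and 4 negative estimates with a median of 0.007 (adjusted p = 0.404, and adjusted p = 0.587 with an estimated correlation), and 9 genes of interferon signal transduction had 6 positive and 3 negative ones with a median of 0.25 (adjusted p = 0.00537, and adjusted p = 0.184 with an estimated correlation). Several genes set beforehand missed the threshold by limma: OAS1 had an estimate of 4.13 ± 0.53 (adjusted p = 0.0529), ISG15 of 4.32 ± 0.58 (adjusted p = 0.0643), IFI27 of 3.57 ± 0.98 (adjusted p = 0.305) and SOCS1 of 0.72 ± 0.23 (adjusted p = 0.376). MX1, at the floor on 1 untreated array, and CXCL10 and USP18, at it on both, also missed it. Their estimates were at least 30.7-fold (adjusted p = 0.0960), at least 13.0-fold (adjusted p = 0.218) and at least 15.9-fold (adjusted p = 0.243). This fit counts changes between 4, 8 and 24 h as spread, so a gene that keeps rising can miss the threshold. IFI27, for example, rose by 3.11 from 4 h to 24 h.

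In all, 25 of 13656 genes passed, 17 higher and 8 lower. FOXS1, which encodes a forkhead transcription factor, fell at least 3.35-fold (limma adjusted p = 0.0207), with 5 of 6 treated arrays at the floor. GNG2, a G-protein gamma subunit, fell from 131.4 and 120.3 untreated to between 60.7 and 87.2 (-0.86 ± 0.10, adjusted p = 0.041). SMTNL1, with 4 of 6 treated arrays at the floor, fell at least 1.83-fold and F7, with 3 of 6, at least 1.67-fold. Another 4 genes fell to the floor on all 6 treated arrays: LINC00459 at least 1.65-fold, NRXN2 at least 1.62-fold, TCF7L2 at least 1.61-fold and LINC00563 at least 1.498-fold. Their highest levels were 18.5, 18.5, 18.4 and 16.8, near the floor of 10.7, which left spread only in the 2 untreated arrays. In this order they kept their call in 9, 5, 6 and 5 of 16 settings. Of the 8 genes that fell 7 had no array above 100. The count was 79 without the untreated wild-type array (8 higher and 71 lower, 8 of them among the 25) and 131 without the untreated T387A array (9 higher and 122 lower, 9 of them among the 25), so that lower genes outnumbered higher ones there. It was 14, 0 and 9 without the wild-type array at 4, 8 or 24 h and 0, 3 and 7 without the T387A array at these times. It was 71 without a floor, 64 with a trended and robust prior, and, without both 8 h or both 24 h arrays, 0 and 6.

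With time as 4 levels, a fit chosen after seeing the data, 36 genes rose and 11 fell by 4 h, 110 rose and 19 fell by 8 h, and 111 rose and 28 fell by 24 h (limma, 2 arrays against 2 at each time). Of the 32 antiviral effectors 16 rose by 4 h, 25 by 8 h and 26 by 24 h over all genes tested, and 25, 31 and 29 adjusted over the list alone (adjusted p = 0.235, 0.182 and 0.196 at these times with an estimated correlation). Of 17 genes of class I antigen presentation 0 rose by 4 h by limma, 6 by 8 h and 11 by 24 h, and 5, 12 and 14 adjusted over the list alone, with medians of 0.25, 0.71 and 1.27. By 4 h 13 of the 17 had positive estimates (camera adjusted p = 0.00158; adjusted p = 0.45, 0.182 and 0.196 at the 3 times with an estimated correlation). HLA-B stood at 194.1 and 168.3 untreated, 180.4 and 256.2 at 4 h, and 1180 and 1635 at 24 h in wild type and T387A.

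**Figure D1:**
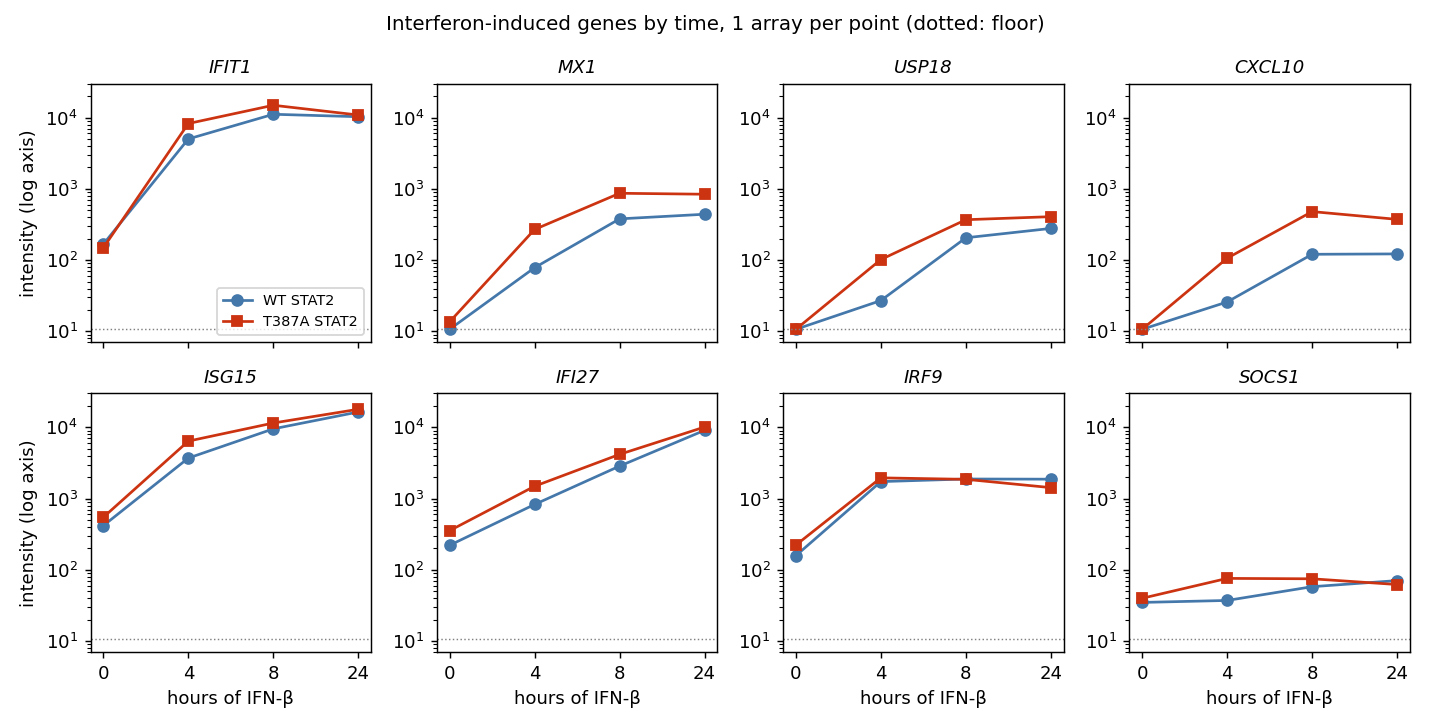
Intensity of 8 interferon-induced genes (log axis, 1 array per point, values under the floor of 10.7 drawn at it) against hours of IFN-β in cells with wild-type STAT2 (circles) and T387A STAT2 (squares); the time points are evenly spaced and not to scale. IFIT1 at 4 h stood at 5021 in wild type and 8262 in T387A, and at 24 h at 10300 and 10880.

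Sterol synthesis and stress response genes were lower at 4 h than at 0 h. By 4 h, 12 of 13 sterol synthesis genes had negative estimates with a median of -0.58; none passed over all genes tested and 9 fell adjusted over the list alone (camera adjusted p = 3.61e-07, and adjusted p = 0.152 with an estimated correlation). DHCR7, which makes cholesterol from its last precursor, stood at 811.3 and 1052 untreated and 391.5 and 478.6 at 4 h in wild type and T387A, and LSS, lanosterol synthase, had an estimate of -0.94 ± 0.11 (adjusted p = 0.067). Of 12 genes of the integrated stress response 1 fell over all genes tested, and 9 fell and 1 rose adjusted over the list alone, with a median of -0.61 (adjusted p = 3.61e-07, and adjusted p = 0.152 with an estimated correlation). That gene was DDIT4, an inhibitor of mTORC1 signalling, at -1.29 ± 0.13 (limma adjusted p = 0.0495). Outside the lists, PTGES, the terminal enzyme of prostaglandin E2 synthesis, fell by 1.80, JUP, the junction protein plakoglobin, by 2.02, FBXO32 by 1.51 and the glucocorticoid-induced TSC22D3 by 1.23; these were chosen after their values were seen. No untreated arrays at 4, 8 or 24 h were used here, so time in culture was not separated from IFN-β.

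In wild-type cells 87 genes were at least 2-fold higher at all 3 times than at 0 h and 57 at least 2-fold lower. The largest mean log2 changes were those of IFIT3 (6.31), OASL (5.64), IFIT1 (5.64), RSAD2 (5.57), IFIT2 (5.49), OAS2 (5.18), MX2 (5.11), IFI6 (4.76), IFI44 (4.72) and RIGI (4.47); RSAD2 and MX2 were at the floor at 0 h, so that theirs are lower bounds. IFIT1 went from 167.4 at 0 h to 5021, 11150 and 10300, and ISG15, the ubiquitin-like modifier, from 417.8 to 3712, 9546 and 16480. The antiviral list had medians of 1.89, 3.41 and 3.68 at 4, 8 and 24 h, each at percentile 100 of the random lists, and class I antigen presentation 0.07, 0.59 and 1.26, at percentiles 84.0, 100 and 100. MYBL2 had the largest mean decrease (-2.25, a bound, with only its 0 h array above the floor), and all 57 lower genes stayed under 100 on every array.

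In T387A cells 103 genes were at least 2-fold higher at all 3 times and 34 at least 2-fold lower. The leading genes were IFIT3 (7.18), RSAD2 (6.82), IFIT2 (6.56), IFIT1 (6.21), OAS2 (6.07), MX2 (5.92), MX1 (5.42), IFIH1 (5.11), RIGI (5.03) and SLC15A3 (4.91), a lysosomal peptide transporter; RSAD2, MX2 and SLC15A3 were at the floor at 0 h. IFIT1 went from 149 to 8262, 14920 and 10880, and ISG15 from 548.1 to 6423, 11530 and 17990. The antiviral medians were 2.62, 4.01 and 3.47 and those of class I antigen presentation 0.49, 0.82 and 1.28, all at percentile 100. Among genes lower at all 3 times by any amount, DMBT1 (-1.76, highest level 138.2), FAM20C (-1.75) and FOXS1 (-1.67, a bound, at the floor at all 3 times) had the largest mean decreases. Of the 34 genes at least 2-fold lower, 33 stayed under 100.

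Both lines shared 63 of the genes at least 2-fold higher at all 3 times and 1 of those lower, FOXS1, where independent lists would share 0.66 and 0.14. Arrays simulated without change gave 1.3 higher genes per line on average (0 to 4 in 100 draws), 2.6 lower genes (0 to 9), and 0 in both lines. In this simulation all genes with a mean level under 50 shared a residual SD of 0.319. Single dim genes had more, such as MYBL2 with 0.77 and ARHGAP15 with 0.745. The simulated counts may therefore be too low, above all for lower genes, which was not tested. The 63 hold OAS1, OAS3, IFIH1, DHX58, TRIM22, GBP1, IRF9, USP18 and TAP1, and 2 of them stayed under 100. The 3 times of a line share its 0 h array, and without a floor the genes lower in wild type, in T387A and in both numbered 0. With the floor at 100, chosen after seeing the data, 34 genes were higher in wild type, 48 in T387A and 32 in both, and 0, 1 and 0 were lower. These settings decide little about the lower genes. The setting without a floor adds an offset that shrinks the falls of dim genes, and the floor at 100 sets genes under 100 on every array to 1 value.

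**Figure D2:**
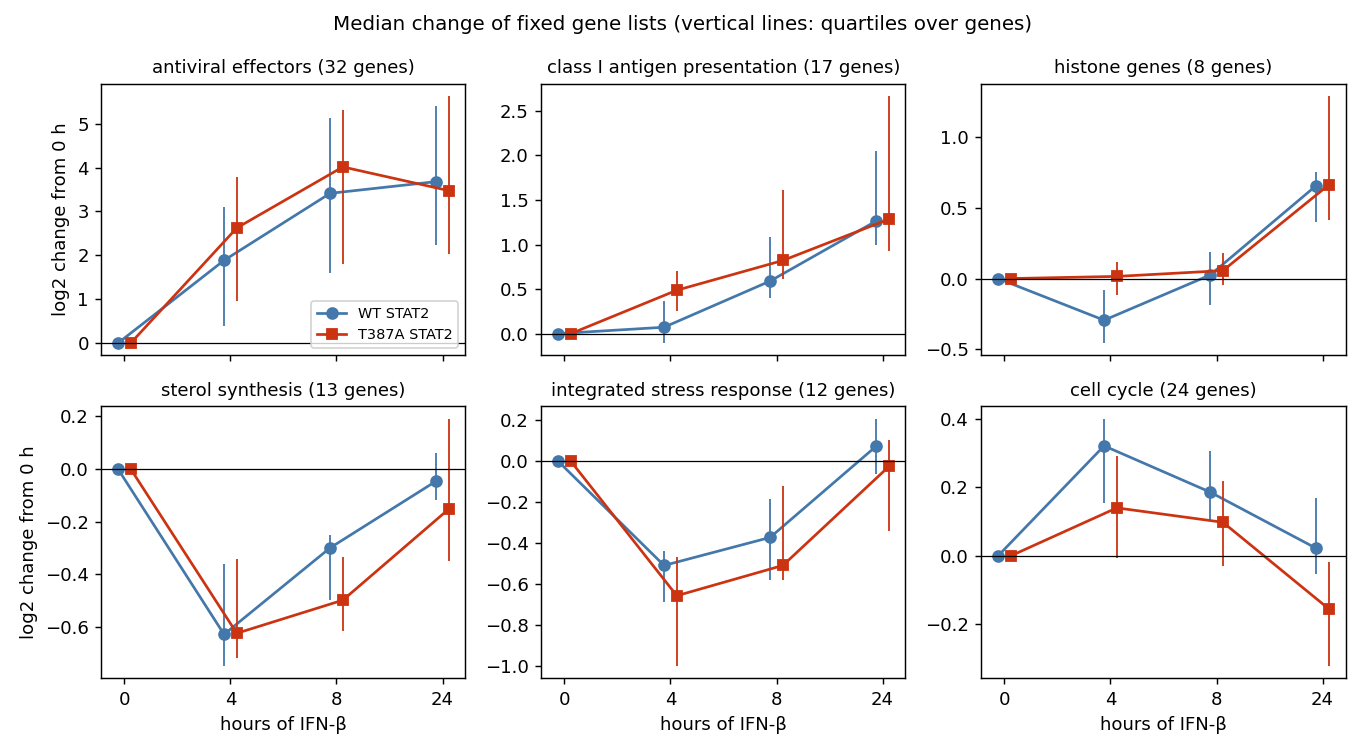
Median log2 change from 0 h of 6 gene lists against hours of IFN-β (evenly spaced, not to scale) in wild-type (circles) and T387A (squares) cells, with vertical lines from the lower to the upper quartile over the genes of a list and separate vertical scales. The antiviral medians reach 3.68 and 3.47 at 24 h, and the sterol synthesis medians lie at -0.63 and -0.62 at 4 h and -0.05 and -0.15 at 24 h.

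From 4 h to 24 h 97 genes rose and 42 fell over both lines. IFI27 rose by 3.11 ± 0.18 (SE, 2 arrays at each time, limma adjusted p = 0.0396), IFI6 by 2.98 ± 0.18, the complement gene CFB by 2.96 ± 0.29, IFITM1, which restricts virus entry, by 2.72 ± 0.13, and HLA-B by 2.69 ± 0.22, a 6.46-fold rise. PLAAT4 (3.23) and IFI44 were also among the 10 largest estimates. So were IFI44L, OTOF and the neutrophil chemokine CXCL8, each at the floor on 1 of the 4 h arrays, which rose at least 15.9-fold, 5.06-fold and 4.92-fold. CERK, ceramide kinase, fell by 1.87 ± 0.17, the complement inhibitor CD59 by 1.60 ± 0.13, PDK3 by 1.55 ± 0.09, and ZC3HAV1, the zinc-finger antiviral protein, by 1.53 ± 0.19 (adjusted p = 0.0495). CGB5, at the floor on 1 of the 24 h arrays, fell at least 5.04-fold. KLC4 fell to the floor on both 24 h arrays, at least 2.82-fold, and LINC02035, USP46, AMY1B and LNPK were the other large falls.

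Of 17 genes of class I antigen presentation 10 rose between these times over all genes and 14 adjusted over the list alone, with a median of 1.03 (camera adjusted p = 2.67e-12, and adjusted p = 0.285 with an estimated correlation). Beside HLA-B these were led by HLA-F (2.21) and the immunoproteasome subunit PSMB9 (1.79), and B2M rose by 1.13. Of 32 antiviral effectors 9 rose and 1 fell over all genes, and 20 rose and 1 fell adjusted over the list alone (adjusted p = 1.6e-12, and adjusted p = 0.339 with an estimated correlation). IFIT3 (0.10) and IFIT2 (-0.59) did not pass. In the integrated stress response 3 of 12 genes rose, and 9 rose and 1 fell adjusted over the list alone, with a median of 0.64 (adjusted p = 7.78e-06, and adjusted p = 0.183 with an estimated correlation); DDIT4 rose by 1.19 and DDIT3, the transcription factor CHOP, by 1.28. None of 13 sterol synthesis genes passed over all genes and 7 rose adjusted over the list alone (adjusted p = 1.95e-05, and adjusted p = 0.183 with an estimated correlation).

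Of these 139 genes, called by limma, 42 had no array above 100. The number called was 0 when both 0 h or both 8 h arrays were left out of the fit, 579 with the floor doubled, 557 without a floor, 722 with a trended and robust prior and 1011 with the floor at 100.

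At 4 h interferon-induced genes stood higher in T387A than in wild-type cells. TNFSF10, the death ligand TRAIL, was at the floor in wild type and at 134.1 in T387A, at least 12.5-fold higher. The helicases DDX60L and DDX60 differed by 2.73 and 2.42 on the log2 scale, TRIM22 by 2.65, the chemokine CXCL10 by 2.04 (25.9 against 106.5), and USP18, the ISG15 protease that restrains interferon receptor signalling, by 1.91 (27.1 against 102). MX1 stood at 78.4 in wild type and 269.7 in T387A. Of the 63 genes induced in both lines 62 were higher in T387A at 4 h, 31 of them at least 2-fold, with a median log2 difference of 0.99, a ratio of 1.98.

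The gap was smaller at 8 h and 24 h. Over the 63 genes the median log2 difference was 0.20 at 0 h, 0.99 at 4 h, 0.56 at 8 h and 0.20 at 24 h, and 42, 62, 62 and 56 of them were higher in T387A. The antiviral list differed by 0.12, 0.93, 0.52 and 0.26 at these times, at percentiles 98.9, 100, 100 and 100 of the random lists, and 14 of its 32 genes were at least 2-fold higher in T387A at 4 h and 3 at 24 h. ISG15 conjugation differed by 0.20, 0.64, 0.37 and 0.14, nucleic acid sensing by 0.00, 0.74, 0.54 and 0.19, and class I antigen presentation by 0.12, 0.47, 0.46 and 0.29. Of single genes, IFIT1 differed by -0.17, 0.72, 0.42 and 0.08, ISG15 by 0.39, 0.79, 0.27 and 0.13, OAS1 by 0.18, 1.07, 0.47 and 0.43, IFI27 by 0.68, 0.85, 0.55 and 0.15, and SOCS1 by 0.19, 1.03, 0.37 and -0.18. CXCL10 still differed by 1.99 at 8 h and 1.61 at 24 h, and GBP4 (2.20), LGALS9 (1.88) and TNFSF10 (1.84) were next to it among the interferon-induced genes at 8 h. IRF9 differed by 0.49 at 0 h and by 0.18, -0.02 and -0.39 after it.

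**Figure D3:**
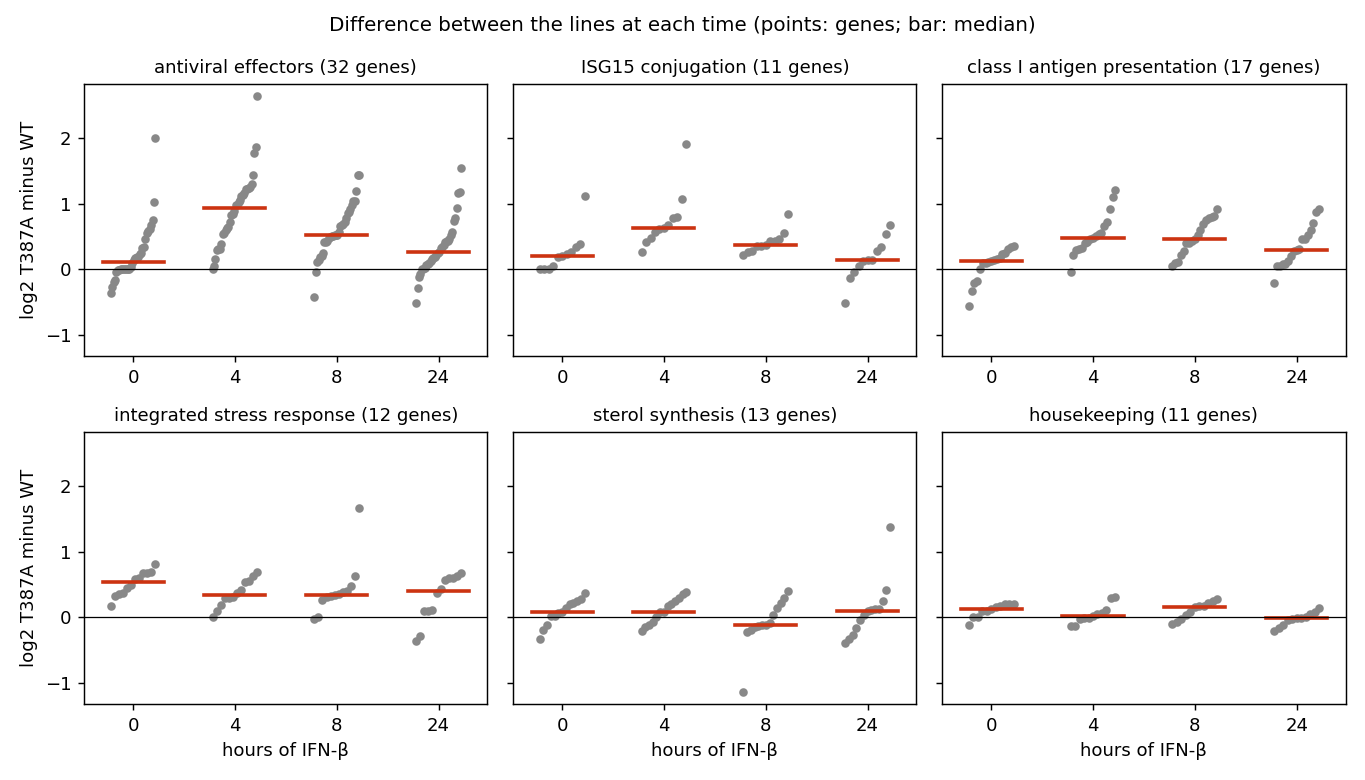
Log2 difference T387A minus wild type of each gene (points) of 6 gene lists at 0, 4, 8 and 24 h of IFN-β, 1 array per line and time, with the list median as a bar. The antiviral median is 0.12 at 0 h, 0.93 at 4 h and 0.26 at 24 h, and that of the housekeeping list is 0.12, 0.02, 0.16 and -0.02 at the 4 times.

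Over all genes, 330, 381, 231 and 582 were at least 2-fold apart between the lines at 0, 4, 8 and 24 h. Of these, 321, 334, 209 and 561 had none of the 8 arrays above 100. With the floor at 100 the counts were 0, 23, 10 and 8. All 23 at 4 h were higher in T387A, and 21 of them were among the 63 genes induced in both lines. At 0 h the largest differences were OASL, higher in T387A by 2.01 (11.4 against 46.0), and MYBL2, which differed by -2.17 (51.0 against 11.3). MAGEA1, a cancer-testis antigen, differed by -1.71, -1.65, -1.58 and -1.95 at the 4 times. At 24 h GATD1 and MST1 had the largest negative differences, -2.31 and -2.29, and IL18BP the largest positive one, 2.24. Each of these differences compares 1 array with 1 and 1 cell line with 1, so none has a replicate check.

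No gene differed between the lines over all 4 times by limma at an adjusted p under 0.05, although 1496 had an unadjusted p under 0.05. MAGEA1 had the smallest adjusted p, 0.0871, with levels of 76.4 to 107.5 in wild type and 23.2 to 36.0 in T387A (-1.72 ± 0.09, lower at 4 of 4 times). Of 32 antiviral effectors 0 passed over all genes and 14 were higher in T387A adjusted over the list alone, with a median of 0.46 (camera adjusted p = 1.29e-14, and adjusted p = 0.37 with an estimated correlation). Of 17 genes of class I antigen presentation 0 passed over all genes and 7 were higher adjusted over the list alone, all 17 had positive estimates, and the median was 0.34 (adjusted p = 3e-09, and adjusted p = 0.37 with an estimated correlation).

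The integrated stress response also stood higher in T387A, without IFN-β as well as with it. All 12 genes had positive estimates, 0 passed over all genes by limma and 7 were higher adjusted over the list alone, with a median of 0.44 (camera adjusted p = 7.06e-10, and adjusted p = 0.178 with an estimated correlation). ASNS, asparagine synthetase, differed by 0.61, 0.64, 0.63 and 0.60 at 0, 4, 8 and 24 h (mean 0.62 ± 0.06, limma adjusted p = 0.285), and TRIB3 by 0.68, 0.55, 0.27 and 0.60. An exact sign-flip test of a list's mean over 4 times cannot go below p = 0.125 two-sided, which is what 14 of 29 lists gave, 10 higher and 4 lower in T387A, the antiviral, class I and integrated stress response lists among them (adjusted p = 0.259). Of the 10 lists that camera called between the lines, 8 were higher in T387A and 2 lower. The lower ones were p53 targets, with 10 of 11 estimates negative and a median of -0.11 (adjusted p = 0.01), and hypoxia and glycolysis, with 10 of 14 negative and a median of -0.05 (adjusted p = 0.0346; adjusted p = 0.37 for each with an estimated correlation). Genes passing numbered 1 with the floor doubled, 8 without a floor, 1 with 4 arrays required above the floor, 2 with a trended and robust prior and 10 with the floor at 100.

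The test of whether the response to IFN-β differed between the lines called 102 genes, 68 with a positive and 34 with a negative difference of T387A minus wild type, and none of them was an antiviral effector. CA13, a carbonic anhydrase, led with a difference of 2.42 ± 0.27 (limma adjusted p = 0.0452) and WIPI2, an autophagy protein, with -2.16 ± 0.21 (adjusted p = 0.0333). All 102 had no array above 100, and in 89 of them the 0 h array of 1 line was above the floor and that of the other at it. Without a floor and with an offset of 16 limma called 0 genes, with a smallest adjusted p of 1.0 and 314 genes at an unadjusted p under 0.05, and it called 1 with the floor kept and the same offset, chosen after seeing the data. The count was also 0 with the floor doubled, with 4 arrays required above the floor, with a trended and robust prior and with the floor at 100. The antiviral list had a median difference of 0.29 in this test, with 25 positive and 7 negative estimates (camera adjusted p = 0.608, and adjusted p = 0.99 with an estimated correlation). This fit does not take out the changes between 4, 8 and 24 h that the lines share. With time as 4 levels, chosen after seeing the data, limma called 0 genes (1087 at an unadjusted p under 0.05). Camera gave in that fit an adjusted p of 0.00108 for the antiviral list and 7.77e-05 for class I antigen presentation (adjusted p = 0.759 for each with an estimated correlation).

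Lists of other cell types and of steady functions were compared as well. Of 12 leukocyte genes 7 were tested and 4 were under the floor on all arrays. A gene at the floor on both arrays has a difference of 0.00, so a median of 0.00 may not measure a lack of change. The leukocyte list had medians of 0.00 at each time in wild type and of 0.00, 0.00 and 0.21 in T387A, and over both lines -0.14 by 8 h (camera adjusted p = 0.378, and adjusted p = 0.566 with an estimated correlation). It differed between the lines by -0.31 at 4 h at percentile 1.96, and by 0.00 at 0 and 8 h. The endothelial list, with 3 genes measured, had a median of -0.48 by 4 h over both lines (adjusted p = 0.118, and adjusted p = 0.34 with an estimated correlation), and differed between the lines by -0.32 at 4 h at percentile 5.66, and the epithelial list by 0.08 at percentile 84.8. Mean differences at 0, 4, 8 and 24 h were -0.157, -0.257, -0.021 and 0.18 for the leukocyte list. They were 0.093, -0.255, -0.296 and -0.165 for the endothelial list and -0.099, 0.003, 0.128 and -0.25 for the epithelial list. The cytosolic ribosomal proteins differed between the lines by -0.06, -0.05, -0.08 and 0.00 and the respiratory chain by -0.04, -0.01, 0.02 and -0.02 at 0, 4, 8 and 24 h.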

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

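The test of the floor on the genes below was chosen only after the result was seen, as were both counts of other splits.

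The difference of the IFN-β response, T387A minus wild type, passed limma's test for 102 genes. The largest positive differences were CA13 at 2.42, MYBL2 at 2.17, CHRNB4 at 2.17, KREMEN1 at 2.17, TBCEL at 1.99, ZNF860 at 1.92, ABCA8 at 1.89, SGMS1 at 1.69, KLHDC10 at 1.51 and SIRT3 at 1.5. The largest negative ones were WIPI2 at -2.16, LMBR1L at -2.07, CDCP1 at -1.82, THSD4 at -1.77, KLKB1 at -1.75, ZNF681 at -1.67, USH1G at -1.6, SGK3 at -1.34, MIR1224 at -1.31 and FDXACB1 at -1.14.

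A candidate explanation for these calls is the floor, which sets dim arrays to 1 common value and so removes their spread. All 102 called genes, 100.0%, had no array above 100, 70 had all 6 treated arrays at the floor, and 0 were called without the floor. In MYBL2 the untreated wild-type array was at 51.0 and the other 7 arrays were at 11.3 or lower. The setting without a floor also adds an offset of 16, which shrinks the differences of dim genes, and with the floor kept and the same offset only 1 of the 102 calls remained. Where all 6 treated arrays were at the floor, the floor left the fit no residual spread, since the fit passes exactly through each single untreated array. The SE of these 70 genes came from the prior alone, and was 0.071 for each of MYBL2, ABCA8, KLHDC10 and ZNF681. Their p-values therefore measure no spread of the genes themselves. How much of the calls comes from the floor and how much from the scale of values near background is not settled by the settings with an offset. A different response of some of these genes stays open too, since each rests on 1 untreated array per line.

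ARHGAP15, GSDMA and LINC02209 moved one way at all 3 times in wild type and the other way at all 3 times in T387A, and their mean responses differed by 2.1, -2.1 and 2.68, T387A minus wild type. The test of the difference of the responses did not pass for them (limma adjusted p = 0.442, 0.861 and 0.226), and none of them had an array above 100.

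Of 8563 probes above the floor that carry no gene name in the probe table, 7 were at least 2-fold higher at all 3 times in both lines. They were left out of every comparison of genes.

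Of the 16 choices of 1 array of each line as the untreated ones, 1, the real one, gave 25 genes in the interferon comparison. The highest other count was 19, from both 24 h arrays, and 16 choices are too few for a share under 0.05. The count was 0 without the wild-type array at 8 h or the T387A array at 4 h. The 32 splits of 4 arrays against 4 with time in the fit decide nothing about chance between the lines, because the real count was 0 and all 32 give at least that; the highest other count was also 0.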

How the results depend on the processing

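The floor at 100, cyclic loess, time as 4 levels, the floor kept with an offset of 16, and the 1.5-fold threshold for genes changed in both lines were chosen only after seeing the data. The signal over background limits what dim genes show: 6352 of the 13656 genes had a mean level under 50, with a residual SD of 0.319 against 0.103 for the genes above 1000. Except where fewer arrays are named, the cause of the moves below was not tested.

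The interferon response over both lines called 25 genes. It called 71 without a floor (65 higher and 6 lower, against 17 and 8), 64 with a trended and robust prior (50 and 14), and 47, 129 and 139 with time as 4 levels at 4, 8 and 24 h. Leaving out arrays gave 0 to 131, and the balance turned from 17 higher and 8 lower to 8 and 71 without the untreated wild-type array and to 9 and 122 without the untreated T387A array. The other settings gave 18 to 35 calls. Between the lines over all times 0 genes were called, and 1 with the floor doubled, 8 without a floor, 1 with 4 arrays above the floor, 2 with the trended prior and 10 with the floor at 100; leaving out any time, scaling, cyclic loess, mean probes and a fit without time gave 0. The difference of the responses called 102 genes, with 0 with the floor doubled, without a floor, with 4 arrays above the floor, with the trended prior, with the floor at 100, with time as 4 levels and on leaving out any treated time, 1 with the floor kept and an offset of 16, and 2 with cyclic loess; scaling gave 102 and mean probes 92. The late contrast called 139 genes, 579 with the floor doubled, 557 without a floor, 254 with 4 arrays above the floor, 722 with the trended prior, 1011 with the floor at 100, and 0 without both 0 h or both 8 h arrays, where fewer residual degrees of freedom remain. Scaling, mean probes and cyclic loess gave 128 to 146. The late contrast without 4 h or 24 h and the interferon fits without 0 h do not exist and were not run.

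Genes at least 2-fold higher at all times in wild type numbered 87, and 57 with the floor doubled, 48 without a floor, 34 with the floor at 100 and 222 at 1.5-fold. Lower genes in wild type numbered 57, and 6 with the floor doubled, 0 without a floor, 22 with 4 arrays above the floor, 29 with mean probes, 0 with the floor at 100 and 278 at 1.5-fold. In T387A 103 were higher, and 68 without a floor, 48 with the floor at 100 and 228 at 1.5-fold; 34 were lower, and 7 with the floor doubled, 0 without a floor, 20 with 4 arrays above the floor, 1 with the floor at 100 and 237 at 1.5-fold. In both lines 63 were higher, and 32 with the floor at 100; 1 was lower, and 0 with the floor doubled, without a floor, with 4 arrays above the floor or with the floor at 100, and 18 at 1.5-fold. At 1.5-fold lower genes outnumbered higher ones in each line, unlike at 2-fold.

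Genes at least 2-fold apart between the lines at 0, 4, 8 and 24 h numbered 330, 381, 231 and 582. They numbered 60, 87, 51 and 118 with the floor doubled, 1, 34, 9 and 12 without a floor, 0, 23, 10 and 8 with the floor at 100, and 1416, 1474, 1187 and 1911 at 1.5-fold. With mean probes the counts at 0 and 8 h were 203 and 152. Gene lists called by camera numbered 13 for the interferon response, 10 between the lines and 13 for the late contrast, and 0 in each with an estimated correlation. For the difference of the responses they numbered 0, also with an estimated correlation, and 5 with time as 4 levels at the preset correlation. The antiviral and class I lists did not pass in that last fit with an estimated correlation.

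Of the counts above under the alternatives 49 stayed within 1.5-fold of the value reported and 84 moved. Of the other values, those of single genes, of lists and of counts by direction at single times, 1148 kept their side or stayed near the value reported, 383 were weaker, 16 stronger and 429 moved. In the interferon response IFIT1 ranged from 5.47 to 6.21 with adjusted p from 1.76e-06 to 0.146 and kept its call in 14 of 19 settings. RSAD2 ranged from 2.97 to 6.82, RIGI from 1.86 to 5.03 and RTP4 from 0.93 to 4.46, each keeping its call in 7 of 19, and CXCL10 ranged from 0.80 to 4.64 and USP18 from 1.08 to 4.83, with the lowest value of each of these 5 genes at the floor of 100, which cuts off the untreated levels.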

Other observations

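In this part the tests of an array-wide shift, of the starting level, of the number of lines and of handling were chosen only after the result was seen, as was the fit with each time against 0 h.

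Some genes outside the interferon lists rose by 4 h or 8 h over both lines, by limma with time as 4 levels and 2 arrays against 2. ID3, an inhibitor of basic helix-loop-helix factors that responds to BMP signals, rose by 1.63 ± 0.14 by 4 h (adjusted p = 0.0394) and 2.25 ± 0.14 by 8 h (adjusted p = 0.00977), and stood at 296.0 and 311.5 at 24 h against 164.0 and 163.9 untreated in wild type and T387A. The heat shock genes HSPA1A and HSPA1B rose by 0.98 ± 0.10 and 1.02 ± 0.12 by 8 h (adjusted p = 0.0346 and 0.0409), the 2 of 10 heat shock genes to pass, and 2 of 10 also passed adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.182 with an estimated correlation). HSPA1A stood at 122.2 and 109.2 at 24 h against 90.0 and 96.3 untreated and HSPA1B at 812.9 and 761.6 against 618.7 and 568.7, and by 24 h 0 heat shock genes passed while 9 of 10 had positive estimates (adjusted p = 0.0143, and adjusted p = 0.22 with an estimated correlation). These genes were chosen after their values were seen.

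Other lists separated 24 h from 4 h. Of 8 histone genes 0 rose over all genes by limma and 7 rose adjusted over the list alone, with a median of 0.96 (camera adjusted p = 2.67e-05, and adjusted p = 0.209 with an estimated correlation); H2AC6 and H2BC12, polyadenylated members of the family, had estimates of 1.19 ± 0.16 and 0.75 ± 0.10. All 12 NF-kB targets had positive estimates with a median of 0.51, of which CXCL8 rose over all genes and 2 rose adjusted over the list alone (adjusted p = 3.52e-05, and adjusted p = 0.183 with an estimated correlation). Of 24 cell cycle genes 22 had negative estimates with a median of -0.26, 0 passed over all genes and 2 fell adjusted over the list alone (adjusted p = 2.18e-05, and adjusted p = 0.339 with an estimated correlation). The inflammatory cytokine IL1B stood at 136.7, 52.9, 73.2 and 227.7 in wild type and at 248.8, 103.9, 89.4 and 283.1 in T387A at 0, 4, 8 and 24 h.

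The excess of interferon-induced genes in T387A was largest at 4 h among the times measured. A brightness ceiling that compresses late values is argued against: 53 of the 63 induced genes stayed under 3000 on every array, and their difference dropped by a median of 0.69 from 4 h to 24 h (95% bootstrap interval 0.57 to 0.76, a drop in 49 of 53). The bootstrap intervals here are over genes, which move together, and hold no spread between cultures or arrays. The median gap between the 4 h and the 0 h difference was 0.71 (0.42 to 0.87, above 0 in 55 of 63), larger than an unchanged starting difference would give. Members at the floor on both untreated arrays, RSAD2, RTP4, USP18 and CXCL10 among them, had their 0 h difference set to 0. The gap therefore does not decide about a higher starting level for them, and no value without them is given here. The median difference at 4 h of 8074 other genes at the same mean levels was 0.001, which decides nothing about an array-wide shift before normalization, since the normalization between arrays holds such a median near 0. A faster or stronger start of interferon-driven transcription with T387A STAT2 may account for the pattern, as a hypothesis. It cannot be told apart from another difference between the lines, such as the amount of STAT2 they express, since there was 1 cell line per genotype and 1 array per time.

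Sterol synthesis and integrated stress response genes were lower at 4 h and 8 h and near their untreated level at 24 h. By 8 h 0 of 13 and 0 of 12 passed over all genes by limma, and 5 and 6 fell adjusted over the list alone (camera adjusted p = 2.3e-06 and 0.000349, and adjusted p = 0.182 for each with an estimated correlation). If IFN-β signalling set the size of the drop, it could be larger in T387A, where induction at 4 h was higher. The median gap of the 4 h change over 25 genes, T387A minus wild type, was -0.022 (95% bootstrap interval over genes -0.209 to 0.054), which leaves this open. Handling or fresh medium at the start of treatment may also lower these genes, and cannot be told apart from IFN-β here, as 0 untreated arrays at 4, 8 or 24 h were used.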
